A study of Homo sapiens with 20 samples.

How the data were processed

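Total RNA of ARPE-19 cells was prepared with the Qiagen RNeasy Mini kit, labelled with biotin by in vitro transcription and hybridized to oligonucleotide arrays, per the labels. There were 3 arrays at each of 0, 6, 16, 24, 42 and 60 h and 2 at 1 h, 20 in all. The intensity values are MAS5 signal as deposited by the authors, on a linear scale, per the submitters' processing notes. The version of MAS5 and its detection calls are not given in the sources used here. The mean of each array after trimming its lowest and highest 2% lay between 499.847 and 499.958, so the arrays had been scaled to a common mean. All 20 columns of values belonged to a sample of the design. Array number, with 2 or 3 per time, limits the precision of every comparison.

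Of 54675 probe sets, 41097 carried 1 gene symbol in the platform annotation, 1801 several and 11777 none. Only probe sets with 1 symbol were tested as genes, and those with several or none were used only where every probe set was tested. The 62 control probe sets were left out of the tests. A probe set was kept if it exceeded the array's median in at least 2 arrays, which left 33625, of which 27595 had 1 symbol. Each gene was represented by its kept probe set with the highest mean log2 value, which gave 14238 genes. Values were taken to log2 after adding 18.1, the 25th percentile of the table. This scale understates the change of genes with a low intensity.

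Linear models with 1 mean per time were fitted to all 20 arrays in limma 3.58.1 under R 4.3.3, with an intensity trend in the empirical Bayes prior. Each later time was compared with 0 h (6 comparisons), and each with the time before it (5 steps), by limma's moderated tests, and the whole time course by limma's moderated F test. The p-values were adjusted by the Benjamini and Hochberg method over all genes within each comparison, and an adjusted p under 0.05 counted as changed, rose or fell. The text also gives, for members of a gene list, counts with p adjusted over the list alone. An error after ± is the SE of the fit unless SD is written.

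The 24 gene lists were written from general knowledge, with 634 entries, of which 44 had no probe set of that symbol here and were not analysed. They were: TGF-beta targets, TNF and NF-kappaB targets, cytokines and chemokines, immediate early genes, EMT transcription factors, mesenchymal markers, contractile and actin cytoskeleton genes, epithelial junction and keratin genes, retinal pigment epithelium genes, collagens and matrix structure, matrix proteases and inhibitors, hyaluronan, CD44 and ERM genes, integrins, S phase genes, G2 and M phase genes, interferon response genes, complement genes, cholesterol genes, hypoxia and glycolysis genes, unfolded protein and stress response genes, pathway components of TGF-beta and TNF, and markers of leukocytes, of endothelium, and of melanocytes and neural retina. Some entries had a probe set of that symbol but none that passed the filter, and these were not tested either. Lists with at least 5 measured members were tested at each time with limma's camera at a preset correlation of 0.01, and the p-values were adjusted over the 144 tests. The lists were also tested at each of the 5 steps, with the p-values adjusted over all lists and steps, and the text gives for the steps the lists called at both correlations and the pigment epithelium genes. Camera with a correlation estimated for each list and the fry test were run beside it. A list whose genes move together for reasons other than treatment can be called at the preset correlation and lose that call with the estimated correlation.

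The genes named were chosen by a rule: the 10 largest rises and falls at each time against 0 h and the 5 largest at each step, among genes past the test whose arrays did not overlap, up to 4 members of each list at each time, and a fixed set of known markers. SGK1, IFI44L and TLN1 fell outside the rule and were named after their values were seen, as exceptions in their lists. The model, its filter and pseudocount, the lists, the rule for named genes and all alternatives but the fit without the 6 h and 16 h arrays were chosen before the data were examined.

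The pipeline was tested on simulated data with 200 changed genes among 14238. Over the 11 comparisons it recovered 67.2 to 85.1% of 2-fold changes and 28.4 to 56.7% of 1.41-fold changes, and made at most 9 false calls in a comparison. It called 12 of 12 lists shifted by a log2 value of 0.5 and no other list. The simulated genes varied independently, so this does not test lists whose genes move together. Their scatter was drawn from the fitted model, and far fewer genes were changed than were called in the data (1604 to 7339 per time against 0 h). The shares recovered and the number of false calls therefore do not carry over to the real comparisons.

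The alternatives were: no pseudocount, a floor at the pseudocount, quantile normalization, no filter, a stricter filter (mean percentile rank above 60), every kept probe set tested by itself, no intensity trend, the replicate number as a block, each array left out in turn, only the arrays compared, a change of at least 2-fold, an estimated correlation, and the fit without the 6 h and 16 h arrays. Data preparation and figures used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.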

Results

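ARPE-19, an established human cell line derived from the retinal pigment epithelium, was exposed to TGF together with TNF, and its total RNA was measured on single-colour oligonucleotide arrays at 0 h and at 6 later times up to 60 h. The series follows an epithelial to mesenchymal transition (EMT) over time, per its title. The labels give the first factor only as TGF. Each time had 3 arrays, apart from 1 h, which had 2, so that 20 arrays fell into 7 groups. The untreated 0 h arrays were the background against which every other time was set. No later time had untreated arrays, and no arrays had either factor alone. A change against 0 h therefore holds both the treatment and the time in culture, which cannot be told apart. The labels speak of repeated experiments and do not say whether these were separate cultures, so the p-values measure the spread between arrays, which may be technical. Fold changes are given as log2 fold change ± SE on the log2(intensity + 18.1) scale, from 3 arrays per time or 2 at 1 h, with the adjusted p of limma. A fold change that involves a mean under 18.1 depends on this constant. That applies to changes given below for CCL20, CXCL2, IL1A, FOSB, BCL2A1, TNC, TEK, MMP1, MMP10, COL6A3, TNNC1, BMP4, EDN2, HSD17B2, CNN1, LMOD1, CDH1, CFD, TGM1, SNAI1, LFNG, IL13RA2, WWC2, LINC02401 and XNDC1N. Each value comes from 1 probe set per gene, and other probe sets of a gene often gave a smaller change, and some gave a larger one. For CXCL2 at 1 h the other gave 3.13 and for NFKBIA 1.55, for TNFAIP2 2.97 at 1 h and 3.29 at 6 h, and the 9 others of NRP2 gave 0.72 to 4.85 at 16 h. At least 1 other probe set of ICAM1, ATF3, COL4A3, ERBB4, DIO2, LHX2, OAS3, ITGB4 and ITGB8 also gave a much smaller change at a time given. Larger changes came from another probe set of IRF1 at 1 h (7.56 against 5.18), CXCL8 at 24 h (9.89 against 8.64) and TNFRSF11B at 16 h (6.03 against 5.15).

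The median intensity of an array lay between 59.2 and 81.1. Arrays of the same time correlated at r = 0.982 to 0.987 across probe sets (19 pairs), and arrays of different times at 0.923 to 0.985 (171 pairs). The arrays came in 2 number formats. Values of the 6 arrays of 6 h and 16 h were written with up to 10 digits, and values of the other 14 arrays with up to 7. The ratio of the 3' to the 5' actin control probe sets was at most 1.20 on those 6 arrays and at least 1.27 on the other 14. Every comparison of 6 h or 16 h with another time except 16 h with 6 h therefore also compared the formats. Time and format cannot be told apart from such a comparison by itself.

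**Figure D1:**
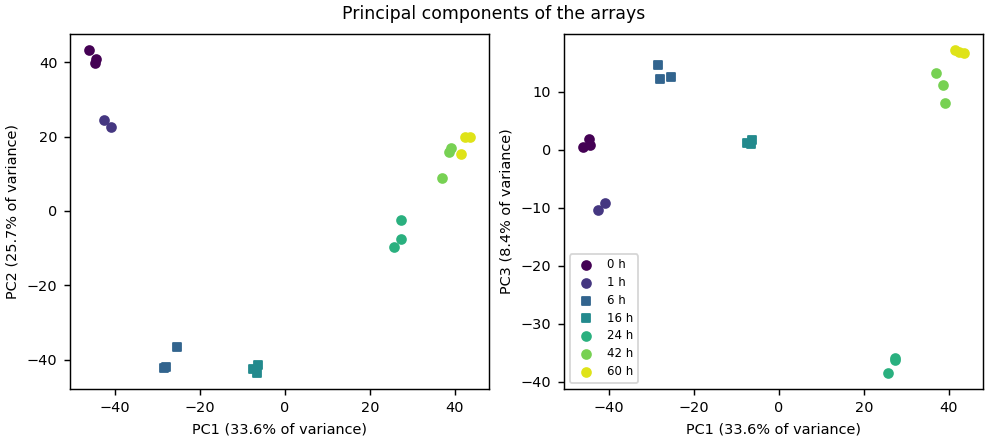
Principal components of the 20 arrays from all 14238 genes tested: component 1 (33.6% of the variance) against component 2 (25.7%, left) and component 3 (8.44%, right), in arbitrary units. Each point is an array coloured by hours of treatment, squares mark the 6 h and 16 h arrays, and component 2 sets those 6 arrays apart from the other 14, while the 3 arrays of 24 h lie apart on component 3.

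Over the whole time course 10784 of 14238 genes (75.7%) changed by limma's moderated F test. Of these, 3959 were at least 2-fold from 0 h at some time. Their largest change came at 1 h for 136 genes, at 6 h for 804, at 16 h for 888, at 24 h for 833, at 42 h for 365 and at 60 h for 933. Of 144 tests of a gene list at a time with limma's camera, 60 were called at the preset correlation of 0.01, and 29 of the 144 with an estimated correlation. The fry test, which asks whether a list's genes move on balance in 1 direction and does not compare them with other genes, called 116, and its test for change in either direction called 140.

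**Figure D2:**
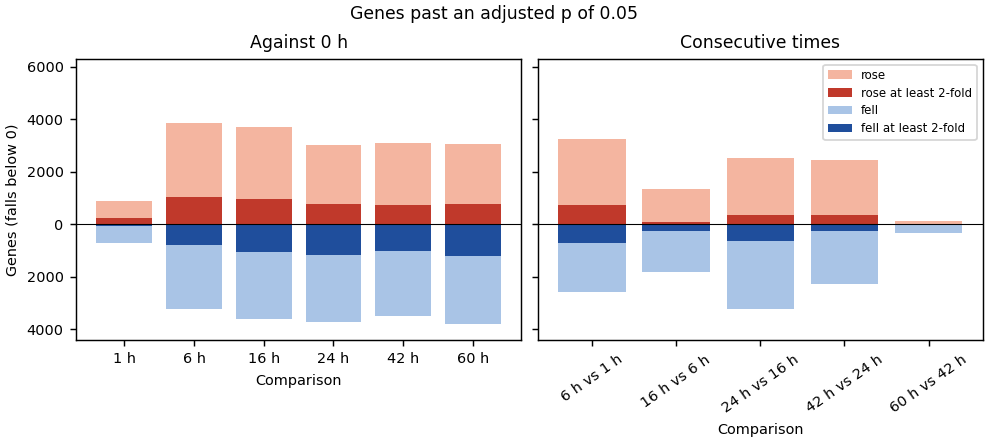
Genes past an adjusted p of 0.05 by limma, of 14238 tested, at each time against 0 h (left) and between consecutive times (right), with rises drawn above 0 and falls below, and the part changed at least 2-fold in the darker colour. The number rose from 1604 at 1 h to 7098 at 6 h and lay between 6600 and 7339 at the later times, and 444 genes differed between 60 h and 42 h.

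The 1 h comparison asked which genes responded earliest. Chemokine genes led the rises. CCL20, which attracts lymphocytes and dendritic cells, rose by 10.30 ± 0.14 (adjusted p = 1.49e-21), from a mean intensity of 3.62 ± 0.0502 (SD, n = 3) to 27424 ± 3186 (SD, n = 2). CXCL2 rose by 8.34 ± 0.16, CXCL8, a neutrophil attractant, by 8.13 ± 0.17, CXCL3 by 7.65 ± 0.27 and CXCL1 by 7.07 ± 0.18. TNFAIP3, an inhibitor of NF-kappaB signalling, rose by 5.86 ± 0.11, and TNFAIP2, PTX3, which codes for a pattern recognition protein, the transcription factor gene IRF1 and the ephrin gene EFNA1 rose by 5.10 to 5.67. TNF itself rose by 3.68 ± 0.37 at 1 h (adjusted p = 4.47e-07) and did not pass the test at any later time. Among the falls were PPP1R3C, which directs a phosphatase to glycogen (-2.84 ± 0.09), the transcriptional coregulator CITED2 (-2.31 ± 0.11), ADM, the gene of the peptide adrenomedullin (-2.06 ± 0.10), and TXNIP, a thioredoxin-binding protein (-1.70 ± 0.09).

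In total 880 genes rose and 724 fell at 1 h, and 222 rose and 54 fell at least 2-fold. Of 21 measured TNF and NF-kappaB target genes, 20 rose (median log2 fold change 1.99, camera adjusted p = 3.26e-55), among them ICAM1, which codes for a leukocyte adhesion molecule (4.46 ± 0.09), and the inhibitor gene NFKBIA (4.41 ± 0.15). Of 23 cytokines and chemokines, 16 rose (camera adjusted p = 3.03e-36). Of 22 immediate early genes, 17 rose, led by FOSB (4.17 ± 0.44), EGR3 (4.05 ± 0.26) and ATF3 (2.76 ± 0.09), and DUSP1 (-0.56) and SGK1 (-0.51) fell (median 1.35, adjusted p = 1.77e-22). Of 24 TGF-beta target genes, 8 rose (adjusted p = 0.00127), with the pseudoreceptor gene BAMBI at 1.67 ± 0.09, the transcriptional regulator genes ID3 at 1.54 ± 0.14 and KLF10 at 1.21 ± 0.10, and SMAD7, an inhibitor of TGF-beta signalling, at 0.75 ± 0.10. Of 24 unfolded protein and stress response genes, 10 rose, such as CHAC1 (2.49 ± 0.29) and DDIT4 (1.06 ± 0.08), and 1 fell (adjusted p = 4.21e-05, and adjusted p = 0.0655 with an estimated correlation). In these 5 lists 20, 16, 18, 8 and 10 members rose adjusted over the list alone.

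OTX2 (-1.41 ± 0.11), SIX3 (-1.07 ± 0.17), MITF (-0.97 ± 0.14) and LHX2 (-0.94 ± 0.20) were among 5 of 22 retinal pigment epithelium genes that fell at 1 h, 5 also adjusted over the list alone (median -0.04, adjusted p = 0.0481, and adjusted p = 0.139 with an estimated correlation). That call was also lost on leaving out any of 10 arrays in turn (adjusted p between 0.0274 and 0.103 over the 20 arrays, the highest without 1 h replicate 0). Of 25 hypoxia and glycolysis genes, 4 fell, 5 adjusted over the list alone (adjusted p = 0.0128, and adjusted p = 0.353 with an estimated correlation), a call also lost without 1 h replicate 0. Of 34 genes of the cell cycle's G2 and M phases, only CCNA2 passed, as lower (-0.40 ± 0.11), and it did not pass adjusted over the list alone or without any of 3 of the 5 arrays in turn. That list was called as lower (median -0.16, adjusted p = 0.0215), which was lost with an estimated correlation (adjusted p = 0.64 with an estimated correlation). Without 1 h replicate 1 the direction of that list turned (adjusted p = 0.707), and without 0 h replicate 0 the call was lost. The count of 1604 changed genes was 801 without 1 h replicate 1, 884 without 1 h replicate 0 and 1040 without 0 h replicate 0.

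At 6 h CXCL8 stood 7.90 ± 0.15 above 0 h (adjusted p = 3.78e-19), TNFAIP2 7.11 ± 0.13, COXFA4L3 6.79 ± 0.13, ICAM1 5.83 ± 0.08, the receptor gene TNFRSF9 5.78 ± 0.09, BCL2A1, a relative of BCL2 that protects from apoptosis, 5.74 ± 0.22, and the signalling adaptor gene TRAF1 5.31 ± 0.12. COXFA4L3 went from 380 ± 17.6 (SD, n = 2) at 1 h to 8527 ± 494 (SD, n = 3) at 6 h, and CCL20 from 27424 ± 3186 (SD, n = 2) to 559 ± 21.7 (SD, n = 3). Among the largest falls were those of TNNC1, a troponin C gene (-4.44 ± 0.32), HSD17B2, an enzyme that inactivates steroid hormones (-4.27 ± 0.24), the transcription factor gene KLF5 (-4.08 ± 0.22), the growth factor gene BMP4 (-3.99 ± 0.28), PPL, which codes for the desmosomal linker periplakin (-3.77 ± 0.23), and the receptor kinase gene ERBB4 (-3.68 ± 0.25). In total 3879 genes rose and 3219 fell, 1025 and 805 of them at least 2-fold.

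Interferon response genes rose at 6 h: of 32, 27 rose and 1, IFI44L, fell (camera adjusted p = 2.33e-12). The immunoproteasome subunit gene PSMB9 rose by 3.63 ± 0.10, and the antiviral genes IFIT3, RSAD2 and OAS1 by 3.60 ± 0.10, 3.03 ± 0.37 and 2.90 ± 0.38. Of the TNF and NF-kappaB targets 19 of 21 rose (adjusted p = 8.49e-19), and of the cytokines and chemokines 20 of 23 (adjusted p = 3.92e-14). DNA replication genes rose as well, with 27 of 29 S phase genes up (median 1.07, adjusted p = 1.94e-11), led by UHRF1 (2.50 ± 0.11) and MCM10 (1.92 ± 0.22). Of the G2 and M phase genes 32 of 34 rose, such as CDC20 (1.79 ± 0.12) and BUB1B (1.67 ± 0.15), with a median of 0.88 (adjusted p = 8.13e-11, and adjusted p = 0.16 with an estimated correlation). The rises in these 5 lists numbered 28, 19, 20, 28 and 33 adjusted over the list alone.

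Matrix genes fell at 6 h. Of 48 collagen and matrix structure genes 23 fell and 7 rose, the same numbers adjusted over the list alone (median -0.31, adjusted p = 3.73e-05). The basement membrane collagen genes COL4A4 (-2.75 ± 0.09) and COL4A3 (-2.36 ± 0.19) and the elastic fibre gene FBLN5 (-2.66 ± 0.15) fell, and the laminin gene LAMB3 rose (2.68 ± 0.15). The pigment epithelium regulators MITF (-2.94 ± 0.13), LHX2 (-2.65 ± 0.18) and PAX6 (-1.80 ± 0.09) fell among 9 of 22 genes of that list, while 4 rose (adjusted p = 0.0321, and adjusted p = 0.11 with an estimated correlation). Of 18 cholesterol synthesis and uptake genes 12 fell, such as INSIG1 (-1.61 ± 0.15) and MSMO1 (-1.26 ± 0.07), and 1 rose (adjusted p = 0.000411, and adjusted p = 0.167 with an estimated correlation). Another probe set of IDI1, at -1.07 ± 0.11 in that list, went the opposite way. Of the hypoxia and glycolysis genes 14 of 25 fell, such as the glucose transporter gene SLC2A3 (-2.24 ± 0.09), and 3 rose (adjusted p = 0.000282, and adjusted p = 0.185 with an estimated correlation). Falls in these last 3 lists numbered 9, 12 and 14 adjusted over the list alone. The 6 h arrays differed from the 0 h arrays in number format and in the actin 3' to 5' ratio. This comparison cannot separate the moves of these lists from those differences.

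At 16 h CXCL8 stood 8.04 ± 0.15 above 0 h, COXFA4L3 7.66 ± 0.13, BCL2A1 6.58 ± 0.22 and TNFRSF11B, which codes for the decoy receptor osteoprotegerin, 5.15 ± 0.23. NRP2, a co-receptor for semaphorins and VEGF, rose by 5.09 ± 0.24 and RARRES1 by 4.96 ± 0.19. HSD17B2 fell by 7.21 (adjusted p = 2.34e-15), from 3022 ± 256 (SD, n = 3) to 2.40 ± 0.928 (SD, n = 3), a level under the pseudocount. PPL fell by 5.23, ERBB4 by 4.96 and DIO2, which activates thyroid hormone, by 4.74. TGFBR3, a TGF-beta co-receptor gene, fell as well (-4.44 ± 0.17). In total 3716 genes rose and 3623 fell at 16 h, 966 and 1042 of them at least 2-fold. The 16 h arrays shared the number format of the 6 h arrays and not that of the 0 h arrays.

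Unfolded protein and stress response genes rose at 16 h. CHAC1, which degrades glutathione, rose by 3.53 ± 0.26, the serine synthesis gene PSAT1 by 2.49 ± 0.08, the asparagine synthetase gene ASNS by 2.40 ± 0.06 and the pseudokinase gene TRIB3 by 2.05 ± 0.08, among 18 of 24 genes of the unfolded protein and stress response list that rose, while 1 fell (median 0.90, camera adjusted p = 1.77e-07). Of the interferon response genes 29 of 32 rose, with PSMB9 at 4.09 ± 0.10 and OAS3 at 3.14 ± 0.13 (adjusted p = 3.51e-13). Of the TNF and NF-kappaB targets 18 of 21 rose (adjusted p = 1.48e-18), and of the cytokines and chemokines 18 of 23, among them the interleukin genes IL1B (4.38 ± 0.08) and IL32 (4.28 ± 0.13; adjusted p = 1.22e-13). Of the G2 and M phase genes 31 of 34 rose and ASPM fell (median 0.90, adjusted p = 6.78e-11, and adjusted p = 0.16 with an estimated correlation). With p adjusted over the list alone, 18, 29, 20, 18 and 31 members of these 5 lists rose. Of the S phase genes 9 of 29 rose and 2 fell, a list not called at 16 h (adjusted p = 0.156).

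Of the 22 immediate early genes 11 rose and 3 fell at 16 h, with JUNB at 1.71 ± 0.11 and FOSL1 at 1.66 ± 0.11 (median 0.46, adjusted p = 0.0194, and adjusted p = 0.198 with an estimated correlation). MITF (-3.41 ± 0.13), LHX2 (-3.13 ± 0.18) and OTX2 (-2.01 ± 0.10) were among 10 retinal pigment epithelium genes that fell, while 4 rose (adjusted p = 0.0399, and adjusted p = 0.126 with an estimated correlation). Of the collagen and matrix genes 18 of 48 fell and 9 rose (median -0.09, adjusted p = 0.0171, and adjusted p = 0.185 with an estimated correlation). Adjusted over the list alone, 11 immediate early genes rose, and 10 pigment epithelium and 19 collagen and matrix genes fell.

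At 24 h the hyaluronan-binding gene TNFAIP6 reached 7.46 ± 0.10 above 0 h (adjusted p = 3.4e-21), with CXCL8 at 8.64 ± 0.15 (39379 ± 6244, SD, n = 3, near the upper limit of the arrays), IL33 at 5.58 ± 0.22, IL1A at 5.46 ± 0.12 and CCL20 at 5.58 ± 0.12. Another probe set of IL1A stood at -0.02. Falls included those of HSD17B2 (-6.05 ± 0.24), PPL (-5.72 ± 0.23), the transglutaminase gene TGM1 (-4.39 ± 0.21), ITGB4, the integrin subunit of hemidesmosomes (-4.32 ± 0.16), the interleukin gene IL18 (-4.29 ± 0.19) and PTGES, a prostaglandin E synthase gene (-4.20 ± 0.16). In total 3036 genes rose and 3710 fell, 772 and 1160 of them at least 2-fold.

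Mitotic genes fell at 24 h. Of 34 G2 and M phase genes 33 fell (median -1.02, camera adjusted p = 5.99e-13, and adjusted p = 0.127 with an estimated correlation), led by the kinesin gene KIF20A (-2.03 ± 0.13), CDKN3 (-1.67 ± 0.11), CKAP2 (-1.58 ± 0.12) and the topoisomerase gene TOP2A (-1.53 ± 0.11). CDC20, an activator of the anaphase-promoting complex, went from 525 ± 59.2 (SD, n = 3) at 0 h to 241 ± 28.3 (SD, n = 3). Of 29 S phase genes 22 rose, such as CCNE2 (1.30 ± 0.14), and 1 fell (median 0.56, adjusted p = 6.27e-06, and adjusted p = 0.0882 with an estimated correlation). When adjusted over the list alone, 33 G2 and M phase genes fell and 22 S phase genes rose.

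Matrix metalloproteinase genes, whose enzymes degrade matrix, rose at 24 h: MMP10 by 4.97 ± 0.26, MMP7 by 4.84 ± 0.26, MMP1 by 4.28 ± 0.32 and MMP9 by 4.13 ± 0.16. Of 34 matrix proteases and inhibitors 20 rose and 8 fell (median 0.60, adjusted p = 5.88e-05). Immediate early genes were high at 24 h, with 15 of 22 up and 4 down (median 1.03, adjusted p = 5.88e-05), among them EGR3 (3.10 ± 0.24), FOSB (2.52 ± 0.39), EGR1 (2.41 ± 0.10) and MAFF (2.31 ± 0.06). EGR1 measured 1958 ± 109 (SD, n = 3) at 0 h, 7448 ± 534 (SD, n = 2) at 1 h, 1326 ± 183 (SD, n = 3) at 6 h and 10520 ± 708 (SD, n = 3) at 24 h. Its arrays still lay between 6438 and 7243 at 42 h and between 4734 and 5733 at 60 h. The stress response list rose, with 20 of 24 genes up and 4 down (median 0.83, adjusted p = 2.13e-07), and TRIB3 reached 3.60 ± 0.08 and ASNS 3.39 ± 0.06. The NF-kappaB targets (20 of 21 up, adjusted p = 2.54e-20), cytokines and chemokines (21 of 23 up, adjusted p = 3.83e-19) and interferon response genes (22 of 32 up and 1 down, adjusted p = 4.56e-09) stayed above 0 h. Rises adjusted over the list alone numbered 23, 15, 20, 20, 21 and 22 in these 6 lists.

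Of 21 mesenchymal markers 10 rose and 3 fell at 24 h. The semaphorin and VEGF co-receptor gene NRP1 rose by 4.72 ± 0.21 and the matrix glycoprotein gene TNC by 4.49 ± 0.24, FN1, the fibronectin gene, by 0.88 ± 0.09 and CDH2, the N-cadherin gene, by 0.44 ± 0.07. The median of that list was -0.01, while its mean was 0.57 and its test pointed up (adjusted p = 0.0155, and adjusted p = 0.0896 with an estimated correlation). VIM, the vimentin gene, did not pass the test at any time and stood at -0.02 ± 0.17 at 24 h and -0.12 ± 0.17 at 60 h, while its other probe set gave -0.79 at 16 h, 0.53 at 42 h and 0.65 at 60 h. VIM measured 38319 ± 1520 (SD, n = 3) at 0 h and FN1 43071 ± 2468 (SD, n = 3) at 24 h. The highest value of an array was 39916 to 68507, so changes of both may be understated near this limit. The 6 other probe sets of FN1 gave 0.63 to 2.42 at 24 h. Of 21 contractile and actin cytoskeleton genes 12 fell and 1, TLN1, rose (median -0.35, adjusted p = 0.0028, and adjusted p = 0.269 with an estimated correlation). CNN1, the calponin gene, fell by 2.96, LMOD1 by 2.58 (its other probe set gave 0.11) and the smooth muscle actin gene ACTA2 by 1.52. MITF was at its lowest at 24 h (-3.66 ± 0.13), with 12 of 22 pigment epithelium genes down and 5 up (adjusted p = 0.0397, and adjusted p = 0.126 with an estimated correlation). Of the cholesterol genes 11 of 18 rose and 1 fell (adjusted p = 0.0155, and adjusted p = 0.311 with an estimated correlation), and of the hypoxia and glycolysis genes 15 of 25 fell and 2 rose (adjusted p = 0.0028, and adjusted p = 0.27 with an estimated correlation). Adjusted over the list alone, 10 mesenchymal markers and 11 cholesterol genes rose, and 12 contractile, 13 pigment epithelium and 15 hypoxia and glycolysis genes fell.

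**Figure D3:**
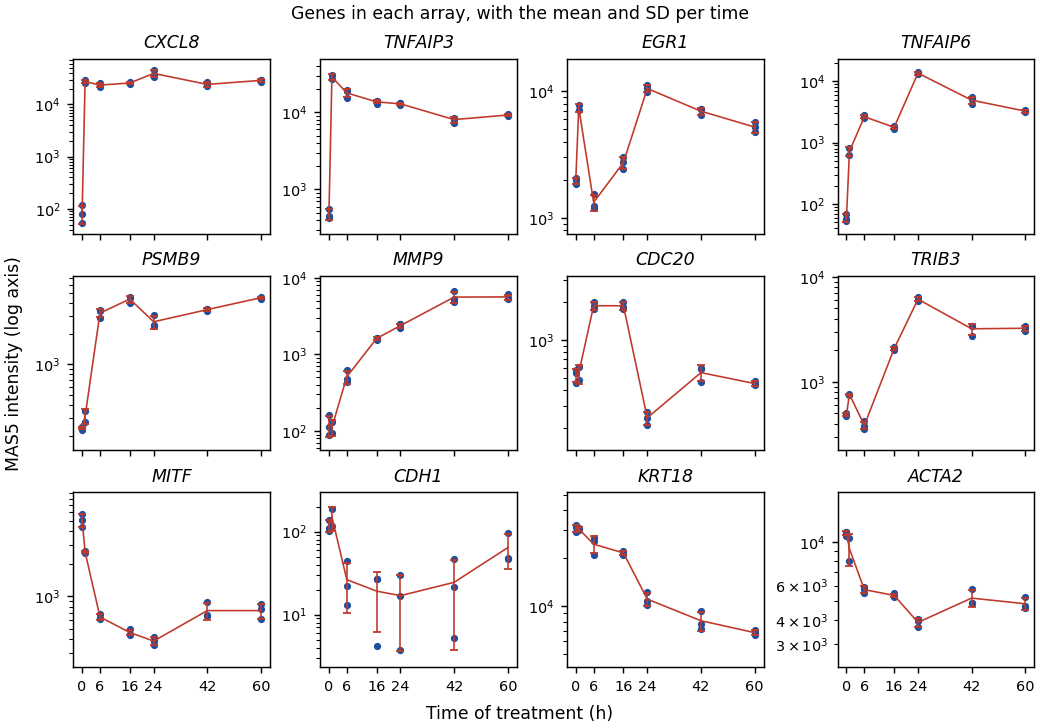
MAS5 intensity on a log axis of 12 genes in each of the 20 arrays (points) against hours of treatment, with the mean and SD per time (line and bars; n = 3, or 2 at 1 h). CXCL8 and TNFAIP3 rose by 1 h, MMP9 rose from 6 h to 42 h, CDC20 was low at 24 h, EGR1 was high at 1 h and 24 h, and MITF fell at every time.

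At 42 h matrix metalloproteinase genes had joined CXCL8 (7.94 ± 0.15) at the top of the rises. MMP10 stood 6.65 ± 0.26 above 0 h (adjusted p = 2.14e-14), MMP1 6.20 ± 0.32, MMP7 5.96 ± 0.26 and MMP9 5.35 ± 0.16. MMP10 measured 3.62 ± 0.825 (SD, n = 3) at 0 h and 2158 ± 113 (SD, n = 3) at 42 h, and since its 0 h level lay under the pseudocount, its fold change depends on it. DIO2 (-4.94 ± 0.13), the membrane glycoprotein gene GPM6A (-4.83 ± 0.30) and the endothelin gene EDN2 (-4.45 ± 0.28) were among the largest falls. In total 3104 genes rose and 3496 fell, 718 and 1032 of them at least 2-fold.

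The protease list was called at 42 h, with 19 of 34 genes up and 9 down (median 0.46, camera adjusted p = 0.000309). Of the NF-kappaB targets 20 of 21 rose (adjusted p = 3.83e-19), of the cytokines and chemokines 20 of 23 (adjusted p = 1.46e-16), of the interferon response genes 22 of 32, with 1 down (adjusted p = 5.23e-09), and of the stress response genes 18 of 24, with 3 down (adjusted p = 5.26e-06). Of the G2 and M phase genes 22 of 34 rose and 1 fell, with HJURP at 1.16 ± 0.11 (median 0.39, adjusted p = 0.000282, and adjusted p = 0.415 with an estimated correlation). Of the cholesterol genes 12 of 18 rose, such as MVD (1.03 ± 0.14) and FDPS (1.00 ± 0.09), and TM7SF2 fell (-1.32 ± 0.13; adjusted p = 0.000205, and adjusted p = 0.157 with an estimated correlation). Of the immediate early genes 13 of 22 rose and 4 fell (adjusted p = 0.00575, and adjusted p = 0.155 with an estimated correlation). The 8 lists had 20, 20, 20, 22, 18, 22, 12 and 13 rises adjusted over the list alone.

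Of the mesenchymal markers 8 of 21 rose and 2 fell at 42 h (median 0.10, adjusted p = 0.0378, and adjusted p = 0.14 with an estimated correlation), with TNC at 4.43 ± 0.24 and the platelet-derived growth factor receptor gene PDGFRB at -1.04 ± 0.09. Among 48 collagen and matrix genes COL6A3 (2.92 ± 0.26) and COL1A2 (2.25 ± 0.19) were among 11 that rose, and FBLN5 (-2.55 ± 0.15) among 25 that fell (median -0.43, adjusted p = 0.0456, and adjusted p = 0.269 with an estimated correlation). That call was also lost on leaving out any of 6 arrays in turn, with an adjusted p between 0.0235 and 0.0726 over the 20 arrays. Of the contractile genes 12 of 21 fell and 2 rose (median -0.26, adjusted p = 0.00291, and adjusted p = 0.269 with an estimated correlation). Of the hypoxia and glycolysis genes 19 of 25 fell, with ADM at -4.27 ± 0.09 and the glucose transporter gene SLC2A1 at -2.29 ± 0.14 (adjusted p = 9.34e-08, and adjusted p = 0.0655 with an estimated correlation). Of the pigment epithelium genes 5 of 22 rose and 10 fell, the same numbers adjusted over the list alone (adjusted p = 0.22). Adjusted over the list alone, 8 mesenchymal markers rose, and 26 collagen and matrix, 13 contractile and 20 hypoxia and glycolysis genes fell.

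At 60 h CXCL8 stood 8.20 ± 0.15 above 0 h, MMP10 7.08 ± 0.26, MMP1 6.66 ± 0.32, the matrix protein gene ABI3BP 6.15 ± 0.12, IL1A 5.74 ± 0.12 (its other probe set gave 0.44) and IL33 5.51 ± 0.22. MMP1 measured 12.2 ± 14.5 (SD, n = 3) at 0 h and 2839 ± 71.6 (SD, n = 3) at 60 h. DIO2 (-4.97 ± 0.13), GPM6A (-4.92 ± 0.30), ADM (-4.88 ± 0.09), TGM1 (-4.65 ± 0.21) and SFRP4, a secreted Wnt antagonist (-4.37 ± 0.12), were among the largest falls. In total 3080 genes rose and 3798 fell, 780 and 1198 of them at least 2-fold.

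Glycolysis and hypoxia genes fell together at 60 h, with 22 of 25 down (median -1.03, camera adjusted p = 7.2e-11), among them the phosphofructokinase regulators PFKFB3 (-2.72 ± 0.12) and PFKFB4 (-2.69 ± 0.14). Contractile genes fell in 16 of 21 cases, such as CNN1 (-1.48 ± 0.28), TPM2 (-1.48 ± 0.13) and MYL9 (-1.24 ± 0.08; median -0.52, adjusted p = 9.54e-05, and adjusted p = 0.16 with an estimated correlation). Of the proteases and inhibitors 21 of 34 rose and 10 fell (median 0.68, adjusted p = 0.000925, and adjusted p = 0.0603 with an estimated correlation). The NF-kappaB targets (20 of 21 up, adjusted p = 1.15e-19), cytokines and chemokines (20 of 23, adjusted p = 4.15e-16), interferon response genes (24 of 32 up and 2 down, adjusted p = 7.85e-11) and stress response genes (19 of 24 up and 3 down, adjusted p = 2.85e-06) stayed above 0 h. Of the cholesterol genes 12 of 18 rose and 1 fell (adjusted p = 0.000935, and adjusted p = 0.185 with an estimated correlation). Of the immediate early genes 11 of 22 rose and 5 fell (adjusted p = 0.0396, and adjusted p = 0.265 with an estimated correlation), a call lost without 0 h replicate 2 and without 60 h replicate 1 (adjusted p = 0.0781 without the latter, and from 0.0198 upwards over the 20 arrays). Adjusted over the list alone, 22 hypoxia and glycolysis and 16 contractile genes fell, and 21, 20, 20, 25, 19, 12 and 11 members of the other 7 lists rose. Of the G2 and M phase genes 3 of 34 rose and 8 fell (adjusted p = 0.851), and of the collagen and matrix genes 11 of 48 rose and 27 fell (adjusted p = 0.0797). Of the pigment epithelium genes 4 of 22 rose and 8 fell, the same numbers adjusted over the list alone (adjusted p = 0.372).

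**Figure D4:**
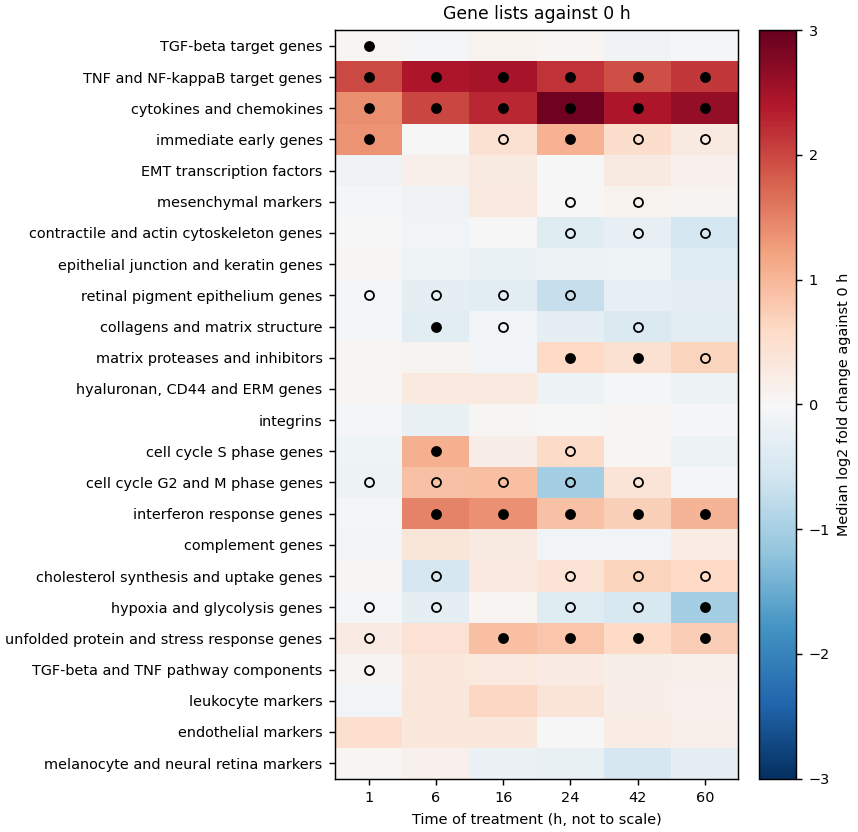
Median log2 fold change against 0 h (colour, scale at right) of 24 gene lists at 1, 6, 16, 24, 42 and 60 h. Open circles mark the list tests called by camera at a correlation of 0.01, and filled circles those also called with an estimated correlation, such as the TNF and NF-kappaB targets at each time. The G2 and M phase list had a median of 0.90 at 16 h, -1.02 at 24 h and 0.39 at 42 h.

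Markers of the epithelial and of the mesenchymal state moved in part. KRT8 and KRT18, the keratin genes of simple epithelia, fell by 2.17 and 2.18 at 60 h. KRT8 had risen at 6 h (0.50 ± 0.08). CDH1, the E-cadherin gene, fell by 1.66, 1.92, 2.02 and 1.78 at 6, 16, 24 and 42 h, and did not pass at 60 h (-0.76 ± 0.42, adjusted p = 0.144). Its intensity was 117 ± 19.6 (SD, n = 3) at 0 h and 26.4, 19.2, 16.9 and 24.5 at those 4 times, under the array medians and near the pseudocount, so the size of these falls is uncertain. CLDN1 and CLDN11, which code for tight junction claudins, rose by 1.99 ± 0.08 and 2.65 ± 0.09 at 60 h. Of 20 epithelial junction and keratin genes 5 rose and 7 fell at 60 h, the same numbers adjusted over the list alone, and the list was called at no time (adjusted p from 0.637 to 0.844). Among 15 EMT transcription factor genes, 4 rose and 4 fell at 60 h, also adjusted over the list alone, and that list was called at no time either (adjusted p from 0.372 to 0.993). SNAI1, which codes for a repressor of E-cadherin, rose by 1.63 ± 0.35 at 24 h and stood at -0.09 ± 0.35 at 60 h. TWIST1 fell by 1.41 at 24 h. ZEB1 fell by 0.80 at 6 h and rose by 0.34 ± 0.07 at 60 h. The TGF-beta target list was called at 1 h alone. At 60 h 9 of its 24 genes rose and 11 fell, also adjusted over the list alone, with ID3 at 2.39 ± 0.13, and ID1 (-3.72 ± 0.17), ID2 (-2.44 ± 0.26) and the oxidase gene NOX4 (-2.78 ± 0.11) lower. The median of that list was -0.07 and its mean -0.22 at 60 h while its test pointed up (adjusted p = 0.995).

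Markers of other cell types were tested as a check on the culture. Only markers with a kept probe set entered it. These were 7 of 16 leukocyte, 6 of 13 endothelial and 5 of 16 melanocyte and neural retina markers. Of 7 measured leukocyte markers 1 rose and 1 fell at 60 h, also adjusted over the list alone, LCP1 by 1.68 ± 0.15 and CSF1R by -0.81 ± 0.14. At 16 h 4 of them rose, also adjusted over the list alone (median 0.62, mean 0.75). The list was called at no time (adjusted p from 0.208, at 16 h, to 0.733). Of 6 endothelial markers 2 rose at 60 h, also adjusted over the list alone (adjusted p from 0.114 to 0.49). ROBO4, a guidance receptor gene of endothelium, rose by 4.18 ± 0.20 at 16 h and 2.62 ± 0.20 at 60 h, where its other probe set gave 1.20 and 0.28. The endothelial receptor kinase gene TEK rose by 2.16 ± 0.35 at 24 h. Of 5 melanocyte and neural retina markers 2 rose and 2 fell at 60 h, with 2 rises and 3 falls adjusted over the list alone (adjusted p from 0.591 to 0.851). The reference genes GAPDH and ACTB, which also lay near the upper limit of the arrays, stood at -0.26 ± 0.15 and -0.12 ± 0.14 at 60 h. GAPDH passed at no time, and ACTB passed at 16 h alone (0.40 ± 0.14, adjusted p = 0.0244), a call lost without 0 h replicate 2 (adjusted p = 0.0961) and without 16 h replicate 0. After quantile normalization ACTB also passed at 6 h and 24 h and GAPDH at 24, 42 and 60 h.

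Between consecutive times the 6 h arrays differed from the 1 h arrays in 5831 genes (3235 up, 2596 down). DNER, a Notch ligand gene, rose by 4.67 ± 0.22, the lipase inhibitor gene ANGPTL4 by 4.34 ± 0.24, NRP2 by 4.30 ± 0.26 and the heme oxygenase gene HMOX1 by 4.12 ± 0.30. CCL20 fell by 5.57, FOSB by 4.35 and EGR3 by 4.12. Called with both correlations were falls of the immediate early genes (17 of 22, and 18 with 1 rise adjusted over the list alone; 0.0103 with an estimated correlation) and of the collagen and matrix genes (25 of 48 with 3 rises, also over the list alone; 0.0249). Rises were called likewise of the S phase genes (26 of 29, and 28 over the list alone; 0.0115) and interferon response genes (26 of 32 with 1 fall, and 27 with 1 over the list alone; 5.54e-05). This step also compared the number formats.

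From 6 h to 16 h 1338 genes rose and 1818 fell, on arrays of 1 format. Among the rises were those of CHAC1 (3.18 ± 0.26), PSAT1 (2.86 ± 0.08), CTH, which makes cysteine (2.61 ± 0.13), and ASNS (2.58 ± 0.06). DIO2 fell by 3.35, ANGPTL4 by 3.05, HSD17B2 by 2.94 and the peptidylarginine deiminase gene PADI2 by 2.87. The S phase genes fell, 25 of 29, also adjusted over the list alone (median -0.85, adjusted p = 0.0103 with an estimated correlation). Called up with both correlations were the mesenchymal markers (10 of 21 with 2 falls, and 11 with 2 over the list alone; 0.0115), the stress response genes (12 of 24 with 2 falls, and 15 with 2; 0.0131), the cholesterol genes (14 of 18 with 1 fall, also over the list alone; 0.0131) and the immediate early genes (10 of 22 with 1 fall, and 14 with 2; 0.0344).

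From 16 h to 24 h 2513 genes rose and 3239 fell, again across the formats. IL13RA2, an interleukin receptor gene, rose by 5.48 ± 0.20, IL33 by 4.75 ± 0.22, RGS4, a regulator of G protein signalling, by 4.37 ± 0.13 and MMP1 by 4.35 ± 0.32. The retinol metabolism gene DHRS3 fell by 3.76, DNER by 3.54, the neuropeptide gene NMU by 3.46 and SFRP4 by 3.36. All 34 G2 and M phase genes fell, also adjusted over the list alone (adjusted p = 0.02 with an estimated correlation), and so did 15 of 32 interferon response genes (15 over the list alone; 0.0115). Proteases and inhibitors rose in 18 of 34 cases with 3 falls (19 with 3 over the list alone; 0.0115), and cytokines and chemokines in 16 of 23 with 3 falls, also over the list alone (0.0286).

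From 24 h to 42 h 2460 genes rose and 2278 fell, on arrays of 1 format. LMOD1 rose by 2.78 ± 0.32 and the teneurin gene TENM2 by 2.26 ± 0.13, and ANGPTL4 fell by 3.68, LFNG, a modifier of Notch receptors, by 2.64 and IL6 by 2.48. The 34 G2 and M phase genes rose, also adjusted over the list alone (adjusted p = 0.02 with an estimated correlation), and 12 of 23 cytokines and chemokines fell while 1 rose, with 12 and 3 over the list alone (0.0311). Of the pigment epithelium genes 9 of 22 rose and 1 fell at this step, with 10 and 1 adjusted over the list alone (adjusted p = 0.0191, and adjusted p = 0.0931 with an estimated correlation). At the steps that ended at 6, 16 and 24 h 4, 3 and 4 of them rose and 6, 4 and 5 fell, with 4, 3 and 4 rises and 6, 7 and 5 falls over the list alone (adjusted p = 0.125, adjusted p = 0.71 and adjusted p = 0.976). From 42 h to 60 h their median was 0.04 (adjusted p = 0.375).

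The last step changed least: 122 genes rose and 322 fell from 42 h to 60 h, and 9 and 7 of them at least 2-fold. NPPB, the gene of B-type natriuretic peptide, fell by 1.68 (adjusted p = 1.66e-05), TGM1 by 1.53 and DIRAS3, a small GTPase gene, by 1.15. Lists called down with both correlations were the hypoxia and glycolysis genes (11 of 25, and 14 adjusted over the list alone; 0.0183 with an estimated correlation), S phase genes (9 of 29, and 13; 0.0249), G2 and M phase genes (15 of 34, and 29; 0.0344) and hyaluronan, CD44 and ERM genes (3 of 19, and 7; 0.0311). The interferon response list was called up, with 1 of 32 genes up and 4 up and 1 down over the list alone (median 0.17, 0.0115).

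The 5 largest rises from 42 h to 60 h, of WWC2 (1.63 ± 0.44), LINC02401 (1.56 ± 0.34), XNDC1N (1.54 ± 0.38), RASGRF1 (1.29 ± 0.27) and SULT1C2 (1.27 ± 0.29), came from mean intensities of 34.2 or less at 42 h, and each lost its call when at least 1 of the 6 arrays was left out. The count of 444 genes was 277 without 42 h replicate 0, 265 without 42 h replicate 1, 224 without 60 h replicate 0 and 280 without 60 h replicate 2. It was 108 from the arrays of 42 h and 60 h alone and 268 without the 6 h and 16 h arrays.

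Changes at different times were compared across genes, which are not independent replicates. The changes at 42 h and 60 h correlated at r = 0.94, where unchanged groups set against the same 0 h arrays gave 0.499 in 20 simulations. Their covariance was 0.577, against 0.0255 in the simulations. At both times 2628 genes rose and 3028 fell, where independent lists would share 671 and 933, and 7 went opposite ways. The changes at 6 h and 60 h correlated at r = 0.496, with 0.499 in the simulations, and had a covariance of 0.298 with 0.0255 in the simulations. At both 6 h and 60 h 1545 genes rose and 1573 fell, where independent lists would share 839 and 859, and 1248 went opposite ways. The 3 arrays of 0 h could not be split into parts of at least 2, so part of each excess may come from the shared 0 h arrays.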

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

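The differences between times and the control intensity in this part were found by rules set in advance, while the covariance test, the tests of collagen genes and the test of the G2 and M phase fall were chosen only after those results were seen.

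Genes of the G2 and M phases, such as CDC20 and KIF20A, moved in opposite directions at different times. Their median log2 change was higher at 6 h, 16 h and 42 h than at 1 h by 1.05, 1.11 and 0.53. It was lower at 24 h than at 6 h (-1.78) and than at 16 h (-1.85), and higher at 42 h than at 24 h (1.36). These stood out as differences between times in a camera test of the difference itself, adjusted over 360 pairs. With an estimated correlation the adjusted p was 0.137, 0.138, 0.336, 0.0573, 0.0400 and 0.0410 in that order. The comparisons of 6 h or 16 h with 1 h or 24 h also crossed the number formats, and that of 42 h with 24 h did not.

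The fall of 33 of 34 G2 and M phase genes at 24 h was weighed against technical causes. The comparison of 24 h with 0 h holds no array of 6 h or 16 h, so a batch of those arrays does not enter it. After quantile normalization 33 of 34 fell. The median log2 change of all genes at 24 h was -0.056 before it and -0.00065 after it, against -1.02 for this list. So small a shift could not have removed the falls, so this test decides nothing about the scaling of arrays to a common mean. A delay or synchrony of the cell cycle may explain a fall in mitotic genes while 22 of 29 S phase genes rose, but no measure of cell number or DNA content was used here to test it.

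Of 18 cholesterol synthesis and uptake genes, such as INSIG1 and MSMO1, 12 fell at 6 h, and 11, 12 and 12 rose at 24, 42 and 60 h, calls of the list that were lost with an estimated correlation (adjusted p of 0.167, 0.311, 0.157 and 0.185). At 16 h 9 rose and 5 fell (adjusted p = 0.457). Their median change exceeded that at 6 h by 0.785 at 24 h, 1.19 at 42 h and 1.09 at 60 h. With an estimated correlation the adjusted p of these differences was 0.0813, 0.0813 and 0.102, and these 3 differences cross the formats. From 6 h to 16 h, on arrays of 1 format, 14 of 18 members rose and 1 fell (median 0.64, adjusted p = 1.69e-13, and adjusted p = 0.0131 with an estimated correlation).

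The 6 h and 16 h arrays stood apart in number format, so a processing batch was weighed as the cause of their changes. Of the 1830 genes changed at least 2-fold at 6 h, 61.9% (95% interval ± 2.23) had the same sign in 60 h against 1 h, a comparison with no array of that format and none of 0 h, and of the 2008 at 16 h 72.8% (± 1.95). The bound against a batch as the whole cause was 60%, which the 6 h value passed by less than its error. The covariance with the 60 h changes, minus that from shared 0 h arrays, was 0.272 (± 0.0252) at 6 h and 0.359 (± 0.0285) at 16 h. It allows only for simulated scatter of those 0 h arrays, so it decides nothing by itself. The intervals given here take genes as independent and leave out the spread between arrays. At 16 h the share with the same sign passed the bound by more than its error. Yet the ratio of the actin control probe sets was lower on every 16 h array than on every 0 h array. It was likewise lower on every 60 h array than on every 1 h array. Genes that follow this ratio could have the same sign in both comparisons, so the share decides nothing about a technical cause. A batch is left open as the cause at 6 h and at 16 h.

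Of 248 genes changed at least 2-fold at 6 h and called at none of 1, 24, 42 and 60 h, 15.7% differed between 16 h and 6 h, which lay between the bounds set and left a batch open for them. Of the 23 collagen and matrix genes that fell at 6 h, 16 were lower at 60 h than at 1 h, a comparison with no shared array, as were 11 of the 25 other members (one-sided Fisher p = 0.0673, with genes taken as independent). Against 0 h without the 6 h and 16 h arrays 17 of the 23 and 26 of all 48 fell, but those share the 0 h arrays. A batch is left open for these genes.

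The spiked hybridization control BioB-5, which no comparison used, had an intensity of 2221 on 24 h replicate 0 and of 512 to 773 on the 19 other arrays, with a highest value of 674 at 0 h. It stood out as a signal outside the main measurement. It is 1 control probe set. The mean log2 intensity of a separate set of hybridization control probe sets was 11.94 on that array, within the range over all arrays (11.88 to 12.43).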

How the results depend on the processing

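The fit without the 6 h and 16 h arrays was chosen only after the number formats were seen, and every other alternative before. Of 744 results for named genes under 11385 comparisons with an alternative, 11150 stayed on their side of the threshold, 209 lost the call, 26 gained it and 0 reversed. A change of sign where neither fit passed the test counted as no change. Alternatives that keep the group means, such as no intensity trend or only the arrays compared, could not reverse a result. Of 60 list calls under 1783 comparisons, 1716 stayed, 66 were lost and 1 reversed. In 1200 of these comparisons 1 array was left out, and 1178 of the 1200 stayed. They run over all arrays of the series, most of which belong to neither time compared. Leaving out such an array keeps the fold changes, so the number that stayed overstates stability. Numbers of arrays given above for a lost list call also run over all arrays. For named genes only arrays of the times compared were left out.

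Testing every probe set by itself, which tests more items, called 2929, 14793, 15569, 13033, 12961 and 14117 probe sets at 1, 6, 16, 24, 42 and 60 h against 0 h. It called 12136, 5734, 11362 and 9413 at the steps up to 42 h and 24111 over the whole time course. Asking for a change of at least 2-fold, a stricter demand by construction, left 276, 1830, 2008, 1932, 1750 and 1978 genes at those times, 1437, 360, 987, 635 and 16 at the 5 steps, and 3959 over the whole time course. The step from 42 h to 60 h fell from 444 to 108 genes when only its 6 arrays were fitted and to 268 without the 6 h and 16 h arrays, each with fewer arrays to estimate the spread. With an estimated correlation 29 list tests were called instead of 60.

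Leaving out 1 array at a time gave 801 to 1486 genes at 1 h (1604 with all arrays) and 224 to 366 from 42 h to 60 h (444 with all arrays), with fewer arrays in each fit. Leaving out a 1 h array leaves 1 array there, which is assumed to vary like the other groups. The list test of G2 and M phase genes at 1 h had an adjusted p between 1.47e-07 and 0.707 and turned direction without 1 h replicate 1. The cause was not tested. The other counts stayed within 1.5 times, such as 10565 to 10789 over the whole time course and 58 to 61 list calls.

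The replicate block changed no list call. Of the named genes 5 lost and 4 gained a call, and the counts were 1667, 7268, 7524, 6910, 6731 and 7051 at the times, 5976, 3395, 5973, 4945 and 510 at the steps, and 10895 over the whole time course. The deviations of arrays with the same number correlated at -0.0696 to 0.202 in 57 pairs (mean 0.0327, and -0.0163 in 114 other pairs). Pairing asked for every pair over 0.1, and 11 were, most of them between replicate 1 arrays of 0, 6, 24, 42 and 60 h (0.126 to 0.202), so a link among those is open. Of 20 arrays 9 correlated best with their own number.

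Genes with intensities near the pseudocount, such as those that led the rises from 42 h to 60 h, are limited by signal over background.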

Other observations

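The test of the immediate early genes without the 6 h and 16 h arrays was chosen only after those genes were seen to be high at 24 h, and the test of renewed stimulation was written before its value was computed.

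Integrin genes changed in both directions. ITGA2, which codes for a collagen receptor subunit, rose by 4.92 ± 0.15 at 24 h and 3.83 ± 0.15 at 60 h. ITGB4 fell by 3.73 and ITGB8, a subunit that activates latent TGF-beta, by 3.02 at 60 h. Of 20 measured integrin genes 5 rose and 8 fell at 60 h, also adjusted over the list alone, and the list was called at no time (adjusted p from 0.0976 to 0.903). Among 19 hyaluronan, CD44 and ERM genes TNFAIP6 rose by 5.41 ± 0.10 and LAYN, a hyaluronan receptor gene, by 2.22 ± 0.07 at 60 h, where another probe set of LAYN gave 0.37. CD44 rose by 1.08 ± 0.06 at 24 h, and at 6 h and 16 h another of its probe sets went the opposite way. EZR, the ezrin gene, fell by 1.13 at 24 h. At 60 h 4 of these 19 genes rose and 7 fell, also adjusted over the list alone (adjusted p from 0.0938 to 0.922 over the 6 times).

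Among 11 complement genes CFB rose by 2.93 ± 0.17 at 6 h and C3 by 2.11 ± 0.10 at 16 h, while CFD fell by 2.97 at 24 h, to a mean under the pseudocount. At 60 h 5 rose and 3 fell, with 5 and 4 adjusted over the list alone (adjusted p from 0.211 to 0.883 over the 6 times). Receptors of TGF-beta changed in opposite ways at 24 h: TGFBR2 rose by 2.67 ± 0.08, and TGFBR3 (-4.00 ± 0.17) and TGFBR1 (-0.82 ± 0.07) fell. TGFB1 rose by 1.65 ± 0.11 at 60 h. Of 26 pathway components 6 rose and 1 fell at 1 h, with 7 and 1 adjusted over the list alone (adjusted p = 0.0284, and adjusted p = 0.0619 with an estimated correlation). That call was also lost without 1 h replicate 1, with an adjusted p between 0.0186 and 0.0902 over the arrays left out, and at later times the adjusted p was 0.112 to 0.261.

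Immediate early genes were high at 1 h and at 24 h, and part of them stayed above 0 h at 42 h and 60 h. A renewed stimulation of the cells between 16 h and 24 h, such as a change of medium, was tested as a candidate explanation. Across 14238 genes the changes at 1 h against 0 h and at 24 h against 42 h had a Spearman rho of 0.214. Its 95% interval of ± 0.0163 came from resampled genes, taken as independent, and leaves out the spread between arrays. The bound was 0.2, which was passed by less than this error. That the error should be cleared was required only after the value was seen, and the explanation is left open. Of the 222 genes that rose at least 2-fold at 1 h, 104 were higher and 22 lower at 24 h than at 42 h. The step from 16 h to 24 h, which crosses the formats, had a rho of -0.0631 with the 1 h change, and 78 of the 222 genes rose and 57 fell. The comparison of 24 h with 0 h holds no array of 6 h or 16 h. Without those arrays 14 of 22 immediate early genes rose at 24 h, but this fit keeps the fold changes as they were and decides nothing. At 6 h 9 of the 22 rose and 6 fell (median -0.02), on arrays of the other format, and from 6 h to 16 h, within that format, 10 rose and 1 fell. The drop from 1 h to 6 h itself cannot be told apart from a batch.

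Other splits of the arrays were tried as a test of chance. In each comparison of 3 with 3 arrays the true split was the only 1 of 10 with as many genes, and the other splits gave at most 1 gene. With 10 splits no share under 0.05 can be reached, so chance is neither excluded nor supported there. Over the whole time course 1 of 100 drawn splits, the true grouping, reached 10784 genes, and the highest other gave 310. The 1 h comparisons have 2 arrays and were not split.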
